A study of Mus musculus with 5 samples.

How the data were processed

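Methylation was measured by reduced representation bisulfite sequencing, which reads cytosine methylation in a restriction-digested fraction of the genome, in 4 single hepatocytes and in a reference cell pool from the livers of C57BL/6 mice. Per the labels' protocols, livers were perfused with collagenase, single hepatocytes were picked by hand with capillaries under a microscope, and the DNA was cut with MseI. Carrier nucleic acid was added to the single cells, 2 ng of salmon DNA for cells 1 and 2 and 2 ng of tRNA cDNA for cells 3 and 4. The submitters' processing notes name CASAVA 1.4, Trim Galore 0.2.2, cutadapt 1.0, Bowtie2 2.0.0 and Bismark 0.7.6, and the mouse build mm10. How a window was called different from the pool, and with which thresholds, is not given in the sources used here.

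The deposited data of each cell were 2 lists of genomic bins, called demethylation (less methylated than the pool) and methylation (more methylated than the pool). The deposited score of each call runs from 0 to 1000 and is the authors' own value. Its definition is not given in the sources used here. Demethylation calls had the low scores and methylation calls the high ones, so that the score ran with the methylation level of the cell, and it was used only to describe calls and to rank them within a list. The pool entered only through the authors' calls against it, and its own methylation values were not used here. The sequencing depth and the set of bins covered in each cell are unknown, so no coverage stands behind a score, and no read counts were inferred from scores.

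All 1498 calls of the 8 lists were counted. Of these, 1476 were bins of 10 kb with starts on a grid of 1 kb, and 22 were short entries of 100 bp at 8 fixed positions near chromosome ends, where several calls of a cell can share a position. The short entries were counted as calls, also in the counts and tests per chromosome, but left out of the tests of recurrence, location, clustering and gene lists. Calls lay on 19 chromosomes; chromosome 10 was not analysed here, so every total and every count per chromosome is without it. Coordinates are those of the deposited lists (mm10). Gene positions came from a RefSeq gene table of the same build (GRCm38.p6) with 49997 genes, 47283 of them on the chromosomes used. The table gives the 2 ends of each gene but no strand, exons or sequence.

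The tests of the main comparisons, the gene lists and most alternatives were fixed before the data were examined. The log-linear model, the thinning of calls to equal numbers, the tests between scores, and the tests of recurrent bins on X and in genes, of gene families and of other long genes were added later. The labels name no animal for any cell, so the 4 cells were not treated as independent animals. Values are given per cell, and intervals are exact Clopper-Pearson 95% intervals that cover counting error only. The share of demethylation was compared with equal numbers by a two-sided exact binomial test. Pairs of cells were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 6 pairs, and all cells together by permuting the direction of calls. Such tests compare these libraries, not groups of animals. The carrier divides the cells 2 against 2, a design that cannot give an exact p under 0.333, so values by carrier are described and not tested.

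Positional results were compared with 100000 random placements of the calls of each cell on the 1 kb grid of the same chromosome, between its outermost annotated genes; the p values of these random permutations of positions are called placement permutation p. The smallest two-sided p these can give is 2e-05, and permutations of 100000 draws can give 1e-05. A bin was assigned by its midpoint to a gene end (within 1000 bp of either annotated end), a gene body or intergenic sequence. A call counted for a gene list when its bin overlapped a list gene or the 2000 bp on either side. All cells that called the same bin contributed a call each. Recurrence was also compared with a log-linear model of independent calls on a common set of bins of unknown number, with 2000 parametric bootstraps. Mean scores were compared by two-sided permutation tests.

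Parts of the plan were changed by what the data hold. Placements were to be matched on CpG content, and calls were to be assigned to promoters, exons and introns and described by sequence content. These need the genome sequence and exon positions, which were not used here, so matching was on chromosome alone, gene ends stood in for promoters, and sequence content was not run. Chromosome length, planned as an alternative background for the counts per chromosome, became the main one. Calls in gene-dense sequence were weighed by a matching on chromosome and on 5 classes of gene density (genes within 500 kb), added after the data were seen. Other added choices were counting each bin once, counts per chromosome without the short entries, bins called in 1 cell only, and ranking by extreme instead of high scores. For gene-poor surroundings of the long-gene list, the criterion was first written on the p value without adjustment, by which they do not explain the result (placement permutation p = 0.0159). It was changed after that value was seen to the adjusted p over 16 tests, on which the list had been called, and by which the test does not decide. For genes of 1000 kb or more, the criterion written beforehand was met, but its binomial test counts bins of the same gene as independent, so bootstraps over genes and the ratio without the gene with the most calls were added and left gene length of that size open. The cytochrome P450 family was narrowed after its only match proved to be a gene of another kind.

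Named genes followed a rule fixed in advance. It took up to 15 genes within 2000 bp of a bin called in 2 or more cells, those with the most cells first, and every gene of the fixed lists with a call. It also took, per cell and direction, the 3 calls overlapping a gene with the largest scores, and up to 10 genes with 3 or more calls of a direction. Ties were taken by position. A gene taken by this rule is not reported here. Because the score ran with the methylation level, the lowest scores were used in place of the largest for demethylation, in the ranking of recurrent bins as well. Where a bin touched several protein-coding genes, all were named, and predicted genes were named only for recurrent bins.

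The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed 20240501. The placement test was tested on simulated calls for the share of genic bins, with 1275 calls and 200 runs. It called 5.50% of runs without enrichment, 94.0% of runs with a 1.10-fold and 100% of runs with a 1.25-fold enrichment. These calls were drawn independently, from the chances that the test itself uses. Recurrence, clustering and uneven coverage were not simulated, so the rates need not hold for the real calls. The independence model, tested on 60 simulated sets of lists over 1700 bins, called 3.33% of independent sets and 91.7% of sets in which 50 bins had a raised chance of a call. In the independent sets all bins had the same chance of a call in a cell.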

Results

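The series asked how the DNA methylation of single mouse liver cells departs from that of a pool of liver cells. The data were 1498 bins called different from the reference pool in 4 single hepatocytes, the main metabolic cells of the liver. A call of demethylation means that the cell was less methylated than the pool in a bin of 10 kb, and a call of methylation that it was more methylated. Cell 1 had 623 calls, cell 2 had 515, cell 3 had 267 and cell 4 had 93. Cells 1 and 2 were prepared with salmon DNA as carrier and cells 3 and 4 with tRNA cDNA. Each cell is a single library without a replicate. The depth and the bins covered in each cell are unknown, so the number of calls of a cell is not a rate per bin examined.

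Loss of methylation was the commoner departure from the pool in each of the 4 cells. Cell 1 had 596 demethylation and 27 methylation calls, so that 95.7% of its calls were demethylation (95% interval 93.8 to 97.1%, exact binomial p = 8.82e-141 against equal numbers). Cell 2 had 431 and 84 (83.7%, interval 80.2 to 86.8%, exact binomial p = 3.33e-57), and cell 3 had 186 and 81 (69.7%, interval 63.8 to 75.1%, exact binomial p = 1.14e-10). Cell 4 had 79 and 14 (84.9%, interval 76.0 to 91.5%, exact binomial p = 3.62e-12). Over all cells, 1292 of 1498 calls were demethylation (86.2%, interval 84.4 to 88.0%). Equal numbers are only a yardstick for this excess, because the share due without a bias depends on the pool's levels and the call rule, both unknown here. The tests also count overlapping or neighbouring bins as independent calls.

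Part of this excess lay in bins that several cells shared. Among bins called in 1 cell only, a set chosen after the data were seen, demethylation made up 94.9% of 453 bins in cell 1, 77.2% of 347 in cell 2, 51.2% of 162 in cell 3 and 53.8% of 26 in cell 4. Because the bins taken out were 197 demethylation and 4 methylation bins, shared mostly with the long demethylation lists of cells 1 and 2, the lower shares of cells 3 and 4 do not test the excess.

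**Figure D1:**
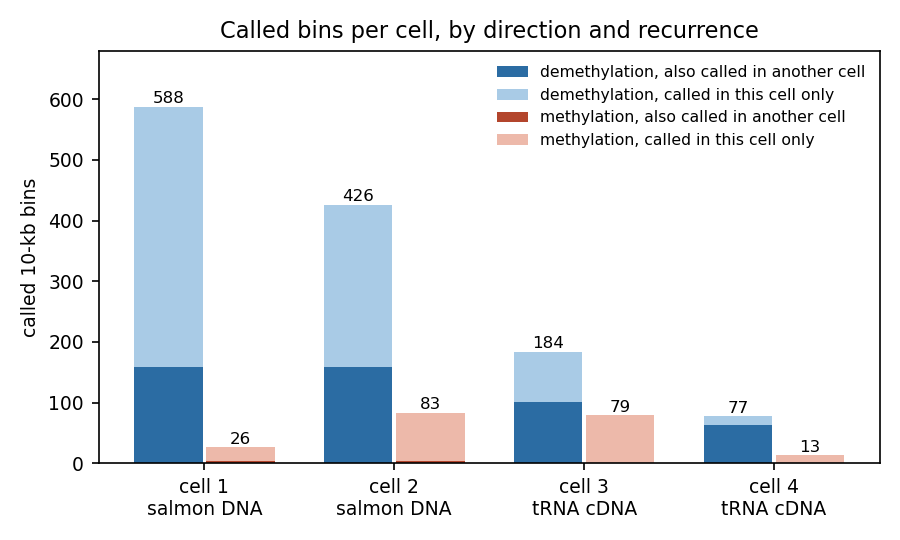
Number of called bins of 10 kb (vertical axis) in each single cell, with its carrier (horizontal axis), for demethylation (blue) and methylation (red); dark parts were also called in another cell, and numbers are totals. Demethylation bins outnumber methylation bins in every cell, and the share also called elsewhere goes from 26.9% in cell 1 to 81.8% in cell 4. Unequal list lengths alone also give an order of this direction.

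The cells differed in the balance of demethylation and methylation calls by more than counting error. The share of demethylation spanned 26.0 percentage points over the 4 cells (permutation p = 1e-05, the smallest these permutations can give). Cell 1 had a higher share than cell 2 (odds ratio 4.30, Fisher's exact adjusted p = 2.89e-11), cell 3 (odds ratio 9.61, Fisher's exact adjusted p = 2.54e-24) and cell 4 (odds ratio 3.91, Fisher's exact adjusted p = 0.000405). Cell 3 had a lower share than cell 2 (odds ratio of cell 2 over cell 3 2.23, Fisher's exact adjusted p = 1.65e-05) and cell 4 (odds ratio of cell 3 over cell 4 0.407, Fisher's exact adjusted p = 0.00476). Cells 2 and 4 did not differ detectably (odds ratio 0.909, Fisher's exact adjusted p = 0.879). The lowest methylation score called was 846 in cell 1, above the median of 833 in each of cells 2 to 4 (lowest 773, 792 and 786). A different call limit may therefore lie behind the high share of cell 1, which was not tested. Demethylation made up 90.2% of calls with the salmon DNA carrier and 73.6% with tRNA cDNA, and the cells within each carrier also differed, as the pairs of cells 1 and 2 and of cells 3 and 4 show.

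Demethylation recurred at the same places in different cells, and methylation did so less often. Of 992 different demethylation bins, 197 (19.9%) were called in 2 or more cells, 56 of them in 3 cells and 15 in all 4. Random placements gave a mean of 0.233 such bins and at most 4 (placement permutation p = 2e-05, the smallest possible). They do not follow the covered bins and give a low estimate of chance overlap. Of 197 methylation bins, 4 (2.03%) were called in 2 cells and 0 in more (placement mean 0.00642, placement permutation p = 2e-05). At equal numbers of calls the gap is smaller, with 11.2 recurrent bins (95% range 6 to 17) for thinned demethylation against 4 (permutation p = 0.0105). No bin was called in opposite directions: 0 of the 201 bins called in 2 or more cells, against 63.0 (95% range 53 to 74) when directions were shuffled within cells (permutation p = 2e-05). This shuffling cannot tell agreement of cells from the shared pool, whose level in a bin may fix the direction that can be called. Demethylation scores reached at most 714 and methylation scores began at 773. Of the 201 bins, 197 are also the recurrent demethylation bins given above.

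The 15 bins demethylated in all 4 cells are given one by one, without a test of what their genes have in common. On chromosome 12, the bin from 82956000 to 82966000 lay inside Rgs6, a regulator of G-protein signalling, with scores of 645, 422, 476 and 188 in cells 1 to 4. The bin from 33738000 to 33748000 on chromosome 11 lay inside Kcnip1, which encodes a potassium channel-interacting protein (scores 571, 286, 533 and 231). The bin from 89630000 to 89640000 on chromosome 3 lay inside Kcnn3, a calcium-activated potassium channel gene (286, 400, 389 and 364). The bin from 91560000 to 91570000 on chromosome 8 lay inside Fto, an RNA demethylase gene linked to body mass (632, 500, 462 and 250).

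Several of these bins covered a gene end. The bin from 88708000 to 88718000 on chromosome 3 held ends of Khdc4, an RNA-binding protein gene, and Rit1, a Ras-related GTPase gene (scores 417, 91, 500 and 250 in cells 1 to 4). The bin from 92018000 to 92028000 on chromosome 2 held an end of Creb3l1, which encodes a transcription factor of the endoplasmic reticulum membrane, beside the non-coding Gm31473 (364, 286, 579 and 250). The bin from 90052000 to 90062000 on chromosome 9 held an end of Ctsh, the lysosomal protease cathepsin H (353, 474, 600 and 273). Ends of Fbxo45, a ubiquitin ligase component, and Wdr53 lay in the bin from 32241000 to 32251000 on chromosome 16 (485, 364, 448 and 267). The small nucleolar RNA Gm25848, within Fbxo45, also lay in it.

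Of the remaining bins called in all cells, that from 27645000 to 27655000 on chromosome 17 lay within 2000 bp of Pacsin1, an endocytosis gene (scores 524, 431, 355 and 192). That from 18030000 to 18040000 on chromosome 13 held the pseudogenes Vdac3-ps1 and Gm6575 (714, 333, 182 and 538). That from 102734000 to 102744000 on chromosome 3, named after its values were seen, held ends of the tetraspanin gene Tspan2 and of Tspan2os (294, 440, 647 and 636). No gene lay within 2000 bp of the other 4, on chromosome 8 from 73411000, chromosome 3 from 82675000 and chromosome 4 from 62871000 and from 63673000.

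The 4 methylation bins called in 2 cells lay inside Gm46298 (chromosome 11, 108868000 to 108878000, scores 862 and 867 in cells 1 and 2), inside Camk1d, a calmodulin-dependent kinase gene (chromosome 2, 5295000 to 5305000, scores 846 and 812 in cells 1 and 2), and at ends of Gm15564 and Kpna1, a nuclear import receptor gene (chromosome 16, 35976000 to 35986000, scores 846 and 833 in cells 1 and 2). The bin from 98294000 to 98304000 on chromosome 12, called in cells 2 and 4, had no gene within 2000 bp. Leaving out cell 1 left 103 recurrent demethylation and 1 recurrent methylation bins, and leaving out cell 2 left 104 and 0.

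The shorter the demethylation list of a cell, the larger was the share of it found elsewhere. Unequal list lengths give such an order even with independent calls, because a short list is set against longer ones. The log-linear model of independent calls fitted 376, 238, 86.6 and 33.9 bins called in cells 1 to 4 alone. Observed were 430, 268, 83 and 14, more than fitted in cells 1 and 2 and fewer in cells 3 and 4. Of the demethylation bins of cell 1, 158 of 588 (26.9%, interval 23.3 to 30.6%) were also called in another cell, against 158 of 426 in cell 2 (37.1%), 101 of 184 in cell 3 (54.9%) and 63 of 77 in cell 4 (81.8%, interval 71.4 to 89.7%). Of the methylation bins, 3 of 26, 4 of 83, 0 of 79 (upper limit 4.56%) and 1 of 13 were, without such an order. Cells 1 and 2 shared 122 demethylation bins, and 130 of the 197 recurrent bins (66.0%) were called with both carriers. The covered bins of each cell are not known, so placements over whole chromosomes give a low estimate of chance overlap, and all cells were called against the same pool, which can also make calls coincide. The log-linear model, added after the data were seen, needs no list of covered bins. It takes all bins as equally open to a call of a given cell, which uneven coverage would break. If calls were independent it fitted 0.710 bins in all cells, against 15 observed, and 25.1 in 3 or more, against 71. Bins called in exactly 2 cells mostly lay below its fit, 64 against 125 for cells 1 and 2, and only cells 2 and 4 reached it (12 against 11.2). The excess over independent calls lay in bins called in 3 or more cells. The fit keeps the total of bins and the list length of each cell. An excess in 3 or more cells therefore brings fewer bins in exactly 2 with it. The low pairs thus say nothing by themselves about sharing between 2 cells. Nor does the model test the 197 recurrent bins as a group. The parametric bootstrap p of the whole fit was 0.0004998, the smallest that 2000 bootstraps can give.

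**Figure D2:**
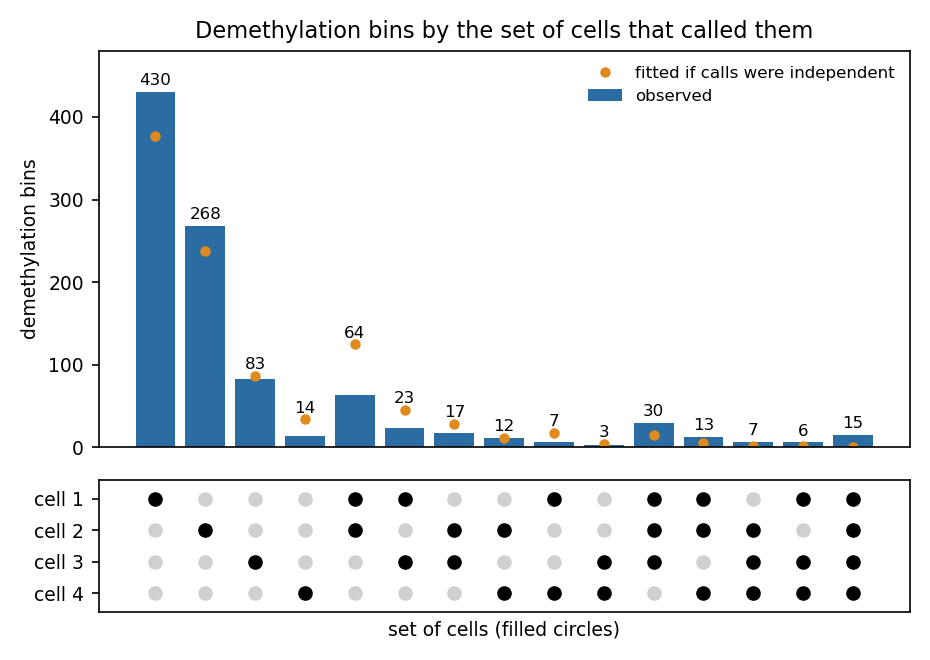
Number of demethylation bins (vertical axis) for each set of cells that called them (filled circles below); bars are observed numbers and points are the numbers fitted if cells called bins independently. The 15 bins called in all 4 cells stand against 0.710 fitted, and bins called in 2 cells mostly lie below the fit. The fit keeps the total and the list lengths, so an excess in more cells brings a lack in 2 with it.

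Most calls lay in genes, with no detectable difference between loss and gain of methylation. Of 1275 demethylation calls of full width, 133 (10.4%) lay at a gene end, 699 (54.8%) in a gene body and 443 (34.7%) between genes. Placements gave 6.40%, 44.6% and 49.0%, ratios of 1.63, 1.23 and 0.709 (adjusted placement permutation p = 4e-05 each). Of 201 methylation calls, 22 lay at a gene end (ratio 1.69, adjusted placement permutation p = 0.0232), 110 in a gene body (1.22, 0.00679) and 69 between genes (0.705, 0.00012). The genic share was 65.3% for demethylation and 65.7% for methylation (odds ratio 0.982, Fisher's exact p = 0.937), and the odds ratio lay on either side of 1 in other settings (0.915 to 1.19). The bins that the assay covered are unknown and placements do not follow them, so these ratios do not separate calls from coverage. Matched also on gene density, a choice made after the data were seen, demethylation calls stayed above placements in gene bodies (ratio 1.10, adjusted placement permutation p = 0.0018) and below them between genes (0.856, 0.00012), while gene ends (1.11, 0.282) and all 3 classes of methylation calls no longer passed. Gene bodies also did not pass for demethylation when any overlap of the bin counted (1.07, 0.114), nor for methylation with any overlap (1.02, 0.862), gene ends of 2000 bp (1.16, 0.0726) or protein-coding genes (1.13, 0.168), nor did methylation at gene ends without cell 3 (1.40, 0.329).

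A number of genes held repeated demethylation calls, 73 of them 3 or more. No gene held 3 or more methylation calls, but with demethylation calls thinned to the numbers of methylation calls a mean of 1.09 genes did (95% range 0 to 4), which does not set the directions apart. Single genes were not tested against chance, and long genes have more room for calls. The immunoglobulin heavy chain locus Igh (chromosome 12, 113258768 to 116009954) had 7 calls in 5 bins over 3 cells. On chromosome 8, the sorting nexin gene Snx25 (46033261 to 46152441) and Tenm3, which encodes a teneurin adhesion protein (48225665 to 49522824), had 6 calls in 4 bins each. Dscaml1, a cell adhesion gene (chromosome 9, 45427433 to 45753713), had 5 calls in 5 different bins, of which 4 were in cell 1. Fbxo45 and Wdr53 had 6 calls in the same 2 overlapping bins, Kcnip1 and Rgs6 had 5 calls in 2 bins each, and Ppp1r12b, a myosin phosphatase subunit gene, had 4 calls in 3 bins.

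The genic bins with the most extreme scores differed from cell to cell. The lowest demethylation scores of cell 1 were in Stpg2 (0), Maml3 (77), a Notch coactivator gene, and Sf1 (83), a splicing factor gene. Those of cell 2 were at Cfap45 (71), the chemokine receptor gene Ccr4 (77) and Smg6 (77), a nuclease gene of nonsense-mediated decay. Those of cell 3 were at Wfdc15b (91), Ncoa5 (143) and Aifm3 (182), and those of cell 4 at Mmd (67), Snx25 (83) and Ergic1 (83). Some of these demethylation bins were also called in another cell with a higher score. They were those at Maml3 (333), Sf1 (455) and Mmd (318) in cell 2, Ncoa5 (364) in cell 1 and Ergic1 (364) in cell 3. The remaining ones were called in a single cell. The highest methylation scores were 909 in cell 1 for Elf2, Pcnx2 and Rnf144b. In cell 2 they were 933 at Lztr1 and Thap7 and 917 at Obp2b and Cux1. In cell 3 they were 1000 in the ubiquitin ligase gene Cbl and in Tfdp2, and 923 in Cntnap5b. In cell 4 they were 917 in Atp9b and 833 at Sh2d7 with Cib2 and at Syngr1.

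No departure from placements was detectable in genes of hepatocyte function. Among 49 hepatocyte secreted and metabolic genes, 2 had demethylation calls: Abcb11, the bile salt export pump, in cell 1, and Hpd, an enzyme of tyrosine breakdown, in overlapping bins of cells 1 and 3. The 3 calls compare with 1.21 in placements (adjusted placement permutation p = 0.81). A methylation call of cell 1 lay at Cpt1a, which brings fatty acids into mitochondria (0.194 in placements, adjusted placement permutation p = 0.81). Of 21 liver transcription factors and 15 genes of the methylation machinery, 0 had a call in either direction, where placements gave 0.487 and 0.393 demethylation and 0.0854 and 0.0535 methylation calls, too few for a lack of calls to show. Imprinted genes with a call were Gnas and Dlk1 (demethylation, cell 1), Trappc9 (demethylation, cell 3) and Zim1 (methylation, cell 3), 3 demethylation calls in 52 genes against 2.28 in placements (adjusted placement permutation p = 1). Of 73 developmental genes, Tbx5 had a demethylation call (1.21 in placements, adjusted placement permutation p = 1). Of 20 cell cycle and ageing-related genes, Atm, the DNA damage kinase, had a methylation call and 0 had a demethylation call.

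Markers of other liver cell types held 5 demethylation calls in 4 of 33 genes, against 1.05 in placements. These were the stellate cell marker Des, the macrophage marker Cd68 and the biliary marker Epcam in cell 1, and Ptprc, which encodes the leukocyte antigen CD45, in different bins of cells 1 and 2. The count did not pass after adjustment over the 16 list tests (ratio 4.76, adjusted placement permutation p = 0.0702). It passed with each bin counted once (adjusted placement permutation p = 0.0339) and without cell 3 (0.0402). It did not pass matched on gene density (ratio 3.13, adjusted placement permutation p = 0.369), with 10 kb around genes (0.19), without cell 2 (0.0816), without cell 4 (0.0578) or without cell 1, where 1 call was left (ratio 1.82, 1). The endothelial marker Kdr had a methylation call in cell 2.

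The list of long and cell adhesion genes was the only list past the threshold of the 16 tests. Its 30 genes held 1 demethylation call, in Cdh13 (chromosome 8, 118517000 to 118527000, cell 1), against 22.7 in placements (ratio 0.0440, adjusted placement permutation p = 0.00032), and 0 methylation calls against 3.58 (adjusted placement permutation p = 0.282). With placements matched on gene density, a choice made after the data were seen, the mean was 6.61 (ratio 0.151, adjusted placement permutation p = 0.255), and 0 lists passed.

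Demethylation calls were spread unevenly over chromosomes. Chromosome 8 held 111 calls where its length would give 67.2 (ratio 1.65, adjusted exact binomial p = 4.24e-06), and chromosomes 5, 11, 15 and 17 also held more (ratios 1.31, 1.40, 1.43 and 1.40). The X chromosome held 29 calls where 88.7 would be in proportion (0.327, adjusted exact binomial p = 1.16e-12) and chromosome 14 held 31 for 64.8 (0.478, adjusted exact binomial p = 1.83e-05), with fewer also on chromosomes 1, 6, 13 and 18 (0.709, 0.733, 0.689 and 0.615). The covered bins of each chromosome are unknown, so an excess or lack of calls is not separated from coverage. The chi-square over all chromosomes was 163 (permutation p = 1e-05), and permutation p was 1e-05, 7e-05, 0.011 and 0.0832 in cells 1 to 4. Methylation calls were also few on X, 2 for 14.2 (ratio 0.141, adjusted exact binomial p = 0.00172). In proportion to the number of annotated genes, a choice made after the data were seen, chromosomes 1, 11, 17 and 18 no longer passed, while chromosome 7 held fewer calls (79 for 114, ratio 0.695, adjusted exact binomial p = 0.00152) and chromosome 12 more (1.32, 0.03). Without cell 1, chromosomes 1, 5, 6, 13, 15, 17 and 18 did not pass, nor did 5 and 11 without cell 2 or 6 and 13 without cell 3, while chromosome 19 passed without cell 2 (1.64, 0.0156) or cell 4 (1.44, 0.0384). With each bin counted once, chromosomes 6, 11, 13 and 18 did not pass, and with bins of full width only chromosomes 12 (1.28, 0.0414) and 19 (1.41, 0.0475) also passed.

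**Figure D3:**
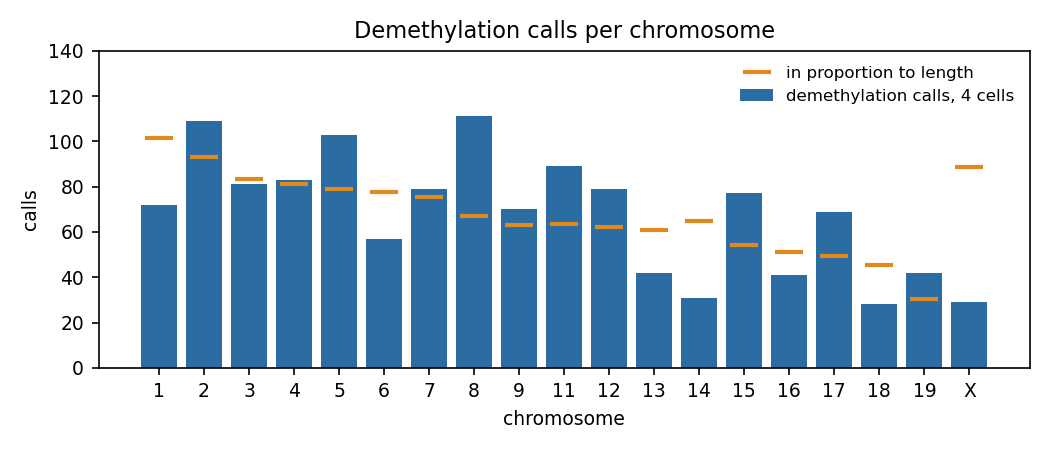
Demethylation calls of the 4 cells together (bars, vertical axis) on each chromosome analysed (horizontal axis), with the number in proportion to chromosome length (orange marks). Chromosome 8 lies above its mark (111 against 67.2) and X below (29 against 88.7).

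Demethylation calls of a cell also lay close together. Of 1275 calls, 61 lay within 10 kb of another demethylation call of the same cell, against 10.4 in placements (placement permutation p = 2e-05). In cell 1, 37 of 588 did, and in cell 2 18 of 426 (placement permutation p = 2e-05 and 0.00016). In cells 3 and 4, 4 and 2 calls did (placement permutation p = 0.0702 and 0.106). Within 100 kb, 20 of 184 calls did in cell 3, against 3.21 in placements (placement permutation p = 2e-05), and 4 of 77 in cell 4 (placement permutation p = 0.0694). Of 201 methylation calls, 0 lay within 10 kb of another (placement mean 0.233) and 2 within 100 kb (placement mean 1.26, placement permutation p = 0.938). Uneven coverage along a chromosome would also bring calls together and is not in the placements. Adjacent bins can be a single change counted more than once: with such bins merged, 1267 demethylation calls were left.

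Scores of demethylation calls were lower in cell 4 than in the other cells. Its mean was 341 (SD 134, 79 calls), against 436, 427 and 450 in cells 1 to 3 (permutation adjusted p = 2e-05 for each pair), and cells 1 to 3 did not differ detectably from each other (smallest permutation adjusted p = 0.096). Median scores were 438, 435, 455 and 333 for demethylation and 862, 833, 833 and 833 for methylation in cells 1 to 4. Demethylation scores spanned 0 to 714 and methylation scores 773 to 1000 over all cells. The limits differed by cell. The highest demethylation scores were 714, 683, 688 and 636 and the lowest methylation scores 846, 773, 792 and 786 in cells 1 to 4.

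**Figure D4:**
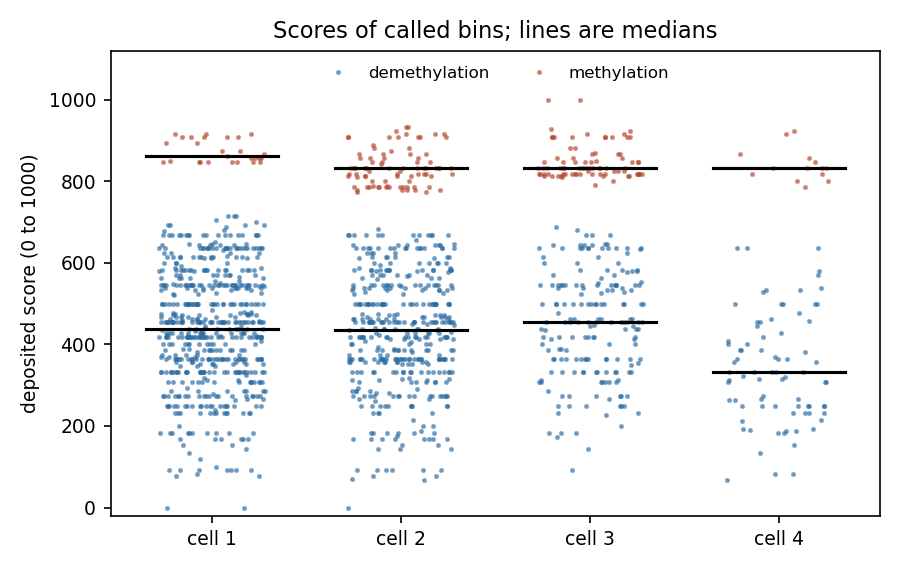
Deposited score (0 to 1000, vertical axis) of each demethylation (blue) and methylation (red) call in each cell (horizontal axis), points spread sideways for visibility, with black lines at the medians. The median for demethylation in cell 4 is 333, against 435 to 455 in the other cells.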

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

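The tests of independent calls, of the carrier, of gene-poor surroundings and of the spread over long genes were chosen after the results they measure were seen. Of 10 values compared over the 4 cells, 2 had a cell far from the others, where chance marks about 1 in 20. Of these 2, the median score of methylation calls was marked only because the other cells were tied.

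The median score of demethylation calls was 333 in cell 4, with the other cells between 435 and 455, a gap of 0.836 of the whole range, just above the limit of Dixon's test. A lower limit, the same in all bins, on the scores that could be called in cell 4 was argued against. With the calls of the other cells limited to 636, the highest score of cell 4, the mean of cell 4 was 341 against 421 (permutation p = 1e-05). The test does not cover a limit set by the distance from the pool's level in each bin. A different set of bins was also argued against, because at the 63 bins that cell 4 shared with another cell its score was lower in 47, with a mean difference of -116 (SD 165, sign-flip permutation p = 1e-05). Both p values are the smallest these permutations can give. Lower methylation of this cell, and more complete conversion or loss of alleles in its library, may each be the cause. A call threshold that depended on coverage or on the pool's level may be as well. All of these stay open, and no biological explanation was tested.

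The median score of methylation calls was 862 in cell 1 (27 calls), with 833 in each of the other cells, a gap as wide as the whole range. Because the other cells are tied, any difference at all would give such a gap, so Dixon's test says nothing here. The lowest methylation score called in cell 1 was 846, above the median of the other cells, so a different call limit may lie behind the difference.

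Demethylation recurred in 197 bins. Independent calls on a common set of bins, all equally open to a call, were argued against by 15 bins in all 4 cells where the independence model fitted 0.710. Its bootstrap p was 0.0004998, the smallest possible. Carrier material as the whole cause was argued against by the 66.0% of recurrent bins called with both carriers. Errors of the common pool stay open: methylation bins recurred 4 times, below the 11.2 (95% range 6 to 17) of demethylation bins thinned to the same numbers (permutation p = 0.0105), but this decides only if the pool errs equally in either direction, which is not known. Bins that vary between liver cells, bins covered more deeply in every library, and bins where the pool is too methylated could each give recurrent calls in the same direction.

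The near absence of demethylation in the list of long and adhesion genes, 1 call against 22.7, may come from gene-poor surroundings in large part. Placements matched on gene density gave 6.61, with a ratio of 0.151 in place of 0.0440 (placement permutation p = 0.0159, adjusted p = 0.255), so the call ended because fewer calls were due, and what remains cannot be told apart from chance over 16 tests, a criterion put in place of the p without adjustment, by which these surroundings do not explain the result, after that p was seen. Gene length above 500 kb as the whole cause was argued against by the other 186 such protein-coding genes, which are shorter than the list's (median 685 against 1241 kb) and held 0.694 of their placements (placement permutation p = 0.00682; 95% bootstrap range over genes 0.382 to 1.03). Gene length of 1000 kb or more stays open, because the ratio of the other 29 such genes, 0.698 (placement permutation p = 0.243), rests on a gene with 6 of 12 calls, is 0.372 without it and has a bootstrap range of 0.122 to 1.45. Matched on gene density both sets held more calls than placements (ratios 1.49 and 1.96, placement permutation p = 0.00622 and 0.0382), so the direction for long genes depends on the background; coverage of the list's genes by the assay stays open, and no biological explanation was tested.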

How the results depend on the processing

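Settings named here as added were chosen after seeing the data. Under the planned and added alternatives, 152 of the values that answer a comparison kept their direction and side of the threshold or stayed within their limits, 11 lost a call, 26 moved beyond their limits and 6 turned, none of these 6 past the threshold on either side. Those that turned were the odds ratio of genic bins, 1.03 with gene ends of 2000 bp, 1.19 with any overlap and for protein-coding genes, 1.03 with each bin counted once (added) and 0.915 to 1.10 without each cell, and methylation calls near each other, 2 within 100 kb. The demethylation excess passed in each cell with adjacent bins merged and on autosomes. With bins called in 1 cell only (added) the share was 51.2% in cell 3 and 53.8% in cell 4, where taking out shared bins removed mostly demethylation. Counting only the higher-scoring portion of each list keeps the shares by construction and tests nothing of the excess; it left 298 demethylation and 13 methylation calls in cell 1, 215 and 42 in cell 2, 93 and 40 in cell 3, 39 and 7 in cell 4, and 645 and 102 in all. Recurrent bins were then 70 for demethylation and 1 for methylation, and 65 and 1 with the most extreme scores (added). Leaving out each cell in turn gave 696 to 1213 demethylation and 122 to 192 methylation calls in all, and 103 to 175 recurrent demethylation and 0 to 4 recurrent methylation bins, fewest demethylation calls without cell 1 and fewest methylation calls without cell 2. With adjacent bins allowed, 4 places were called in opposite directions. In gene bodies, the ratio of methylation calls to placements was 1.16 with gene ends of 2000 bp, 1.13 for protein-coding genes and 1.02 with any overlap, and that of demethylation 1.07 with any overlap, and none of these passed; the cause was not tested. Matched on gene density (added), ratios were 1.11 at gene ends for demethylation and 1.13, 1.09 and 0.857 at gene ends, in gene bodies and between genes for methylation, and none of these passed. The methylation calls are fewer, and in gene bodies and between genes their ratios were close to those of demethylation, which passed (1.10 and 0.856); why the calls ended was not tested. Methylation at gene ends ranged from 1.40 to 1.83 without each cell. The number of lists past the threshold was 2 with each bin counted once (added), 0 matched on gene density (added) and between 1 and 2 without each cell. Unknown depth limits all counts of calls. Of single chromosomes and lists, 20 alternatives lost a call, 7 gained it and 17 turned, of which 1 passed, chromosome 7 by gene number (added). Ratios that turned were 0.973 and 0.996 on chromosomes 4 and 7 among autosomes, 1.20 and 0.695 on chromosomes 3 and 7 by gene number (added) and 0.965 on chromosome 7 with each bin counted once (added), and without each cell 0.922 to 1.09, 0.868 to 1.09, 0.974 to 1.15 and 0.919 to 1.64 on chromosomes 3, 4, 7 and 19. The lists that turned held few calls: liver transcription factors had 1 demethylation call with 10 kb around genes, developmental genes 1 with each bin counted once (added) and 0 to 1 without each cell, imprinted genes 1 to 3, and methylation calls of hepatocyte, imprinted, marker and cell cycle genes were 0 to 1. No paired analysis was possible because the cells form a single group. Matching on CpG content and the sequence content of calls were not run.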

Other observations

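The tests of recurrence on X and in genes and of gene families were chosen after the data were seen, and that of families matched on gene density after its values were seen. Families were named by the prefix of gene symbols. Solute carrier genes had 19 different demethylation bins in 18 of 366 genes, against 10.2 in placements; Slc9b1, a sodium-proton exchanger, was called in 3 cells, Slc35f3 in 2 and the other 16 in 1 cell each. Calcium channel genes had 3 bins against 2.10, in Cacnb2, called in 3 cells, and in Cacnb1 and Cacng2, called in 1 cell each. Glutamate receptor genes had 5 bins against 3.17, in Grm8, Grin2b, Grik5 and Grik4, each called in 1 cell. Cytochrome P450 genes, many of them liver enzymes, had 0 bins in 98 genes, where placements gave 1.96.

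A hypothesis that some gene families hold more or fewer calls was not borne out by placements on the same chromosome: the smallest adjusted p of 11 families was 0.188 (solute carriers, ratio 1.86). Matched on gene density, olfactory receptor genes passed, with 2 bins, at Olfr427 and Olfr315, against 12.7 in placements (ratio 0.157, adjusted placement permutation p = 0.00484). Vomeronasal receptor genes had 0 bins against 4.95 (adjusted placement permutation p = 0.0756). These are clusters of like genes in sequence that the assay may cover thinly, which could not be tested without the covered bins.

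Bins on X were few but recurred more often. Of 16 demethylation bins on X, 8 (50%) were called in 2 or more cells, against 189 (19.4%) of those on autosomes (odds ratio 4.16, interval 1.34 to 12.9, Fisher's exact p = 0.00627). Those near genes lay at Bcorl1, a transcriptional corepressor gene, Bhlhb9, the centriole gene Ofd1, Gm32829 and Gm36522. A candidate explanation is that fewer X bins were open to calls, so that the same bins were drawn more often, and the sex of the animals is not used here. It was not tested. On chromosome 14, which also held few calls for its length, few calls did not go with recurrence (31 calls in 30 different bins). The hypothesis that recurrent bins differ in genic share was left open: 63.5% of recurrent and 66.8% of other demethylation bins were genic (odds ratio 0.863, interval 0.617 to 1.21, Fisher's exact p = 0.401).

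No correlation of scores at shared bins was detectable. Over the 6 pairs of cells, Pearson's r across shared demethylation bins lay between -0.0453 and 0.174 (31 to 122 bins, permutation adjusted p = 0.939 for each), and Spearman's rho between -0.0646 and 0.162 (permutation adjusted p = 0.999 for each). Without the 2 bins farthest from the median, r was 0.209 in place of -0.0453 for cells 3 and 4 and 0.199 for cells 2 and 4. Scores are known for called bins alone, which lowers any correlation, and bins within a cell are not independent replicates. Scores also did not differ detectably between recurrent and other bins of a cell (smallest permutation adjusted p = 0.528).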
